A study of Mus musculus with 12 samples.

How the data were processed

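RNA sequencing was run on splenic B cells sorted by flow cytometry from 6-month-old female mice. Cells positive for B220 and negative for GL7 and CD95 were taken as non-germinal centre (non-GC) B cells, and cells positive for all 3 markers as germinal centre (GC) B cells. The mice carried the lupus susceptibility interval Sle1b on a C57BL/6 background, either with intact Ifnar1, which encodes a chain of the type I interferon receptor, or with Ifnar1 knocked out, per the labels' genotypes B6.Sle1b and B6.Sle1b.IFNaR1-/-. The latter libraries are called Ifnar1KO here. The 12 libraries formed 4 groups of 3: Sle1b non-GC, Sle1b GC, Ifnar1KO non-GC and Ifnar1KO GC. Per the labels' protocols, cDNA was amplified with an ultra-low-input SMARTer kit and made into libraries with Nextera XT. The labels do not say that the libraries of a group came from separate animals. A p-value therefore measures at best the spread between these samples, which may be technical. Tests that set a list of genes against other genes take genes as units, and their p-values do not measure that spread alone.

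Per the submitters' processing notes, CASAVA, Bowtie2 2.1.0, TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff were used with the mouse build GRCm38, also called mm10. Each deposited table compared 1 library with 1 other library of the same batch and gave, for 506504 loci, the FPKM of both libraries as computed and normalized by the authors, together with the authors' p-value and q-value. Of these loci, 45241 carried a gene name and 461263 did not. The 17 tables used covered 3 batches, and the batch number matched the replicate number in all 12 libraries. In batch 1 the direct table of Sle1b non-GC against Sle1b GC cells was not used here, so that ratio was taken through the 5 other tables of the batch. All names of libraries in the tables were matched to a labelled sample.

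Because each table had been normalized on its own, library values were joined within a batch. Loci with the same symbol were summed and symbols that shared a locus were kept together, which gave 43622 items from the named loci. Of these, 9 failed items were left out. The log2 ratios within the tables of a batch were combined by least squares into 1 value of log2(FPKM + 1) per gene and library. Levels in FPKM that are set side by side across batches therefore come from separately normalized tables, and the tests used differences within batches only. A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. A value of exactly 0 can be a failed estimate, so such a gene is said to be listed at 0 and no fold is given against a group listed at 0 throughout. The kit is not stated to keep strand, so overlapping and antisense genes cannot be told apart, and immunoglobulin segments, histocompatibility genes, Gbp genes and pseudogenes share sequence with relatives, which makes their values uncertain.

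Depth was read from the low values. For loci of 800 to 2500 bp, the values were whole multiples of what 1 read is worth, within 0.1 read and up to 5.5 reads, for 98.3% to 100% of low loci in each library. One read on a locus of 1 kb corresponded to 0.117 to 0.387 FPKM. The reads on named genes estimated from this ranged from 1459000 in Sle1b GC replicate 3 to 13647000 in Ifnar1KO GC replicate 1. These estimates describe depth only, and no count test was run on them.

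Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which left 14607. The test was limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a trend on mean expression), two-sided, over all 12 libraries with batch as a block and 6 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons were GC against non-GC in each genotype, Ifnar1KO against Sle1b in each cell type, and the interaction of genotype and cell type. The block rests on the batches that the deposited tables pair libraries within. Libraries of the same batch also deviated together from their group means, with a lowest correlation within a batch of 0.276, 0.399 and 0.525 in batches 1, 2 and 3. The highest correlation with a library of another batch was 0.461 for batches 1 and 2, above their lowest value within a batch, and -0.287 for batch 3. Deviations from a group mean cancel within the group, so a large deviation of batch 3 pushes batches 1 and 2 together. The check thus sets batch 3 apart and cannot show whether batches 1 and 2 differ.

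A total of 30 gene lists was fixed: type I interferon-stimulated genes, interferon-gamma-associated genes, interferon receptor and signalling genes, germinal centre B cell genes, resting and follicular B cell genes, dark zone genes, light zone genes, cell cycle genes, antibody diversification and mismatch repair genes, plasma cell and secretory genes, immunoglobulin constant regions, nucleic acid sensing genes, B cell receptor signalling, cytokine and help receptors, T-bet-associated B cell genes, MHC class II and antigen presentation genes, SLAM family genes, apoptosis regulators, oxidative phosphorylation, glycolysis, Myc-associated growth, marginal zone B cell genes, immediate early and heat shock genes, mitochondrially encoded genes, and markers of T cells, NK and cytotoxic cells, myeloid cells, plasmacytoid dendritic cells, erythroid cells and platelets, and stromal and endothelial cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry tests whether its members move, on balance, one way. The stromal and endothelial list had 2 members past the filter and was not tested as a set. Members past the threshold are counted over all genes and also adjusted over the list alone.

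The genes to name were set by rule: in each comparison of 2 groups, up to 10 genes per direction with the largest change among those past the threshold and with the same sign in all 3 batches, leaving out immunoglobulin variable segments and unnamed loci, or, if none passed, the 5 with the smallest p per direction, said not to pass, with 5 per direction for the interaction, together with Ifnar1 and up to 4 members of each list with the smallest p. The groups, tests, block, lists, naming rule and most alternatives were chosen before the data were examined. A fit to the 8 libraries of batches 1 and 2 was added after seeing the data, with the filter applied to those libraries (12257 genes, 3 residual degrees of freedom), because batch 3 held many more reads on unnamed loci. Genes and list members named from that fit were chosen after their values were seen. A restriction of the interferon-stimulated list to members with a mean of at least 10 FPKM was also added after seeing the data.

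The test was tried on simulated data with the real means and each gene's own residual spread. Among 50 genes changed by 4 on the log2 scale, the step over 14607 genes recovered 76% for GC against non-GC in Sle1b, 82% for the same comparison in Ifnar1KO, 62% for genotype in non-GC cells and 78% for genotype in GC cells. For a log2 change of 2 these shares were 28%, 12%, 4% and 12%, and for a change of 1 they were 0% in all 4 comparisons. Besides the changed genes, 1, 2, 2 and 3 genes without a simulated change were called in these comparisons. The fit to batches 1 and 2 recovered 38%, 34%, 46% and 48% for a change of 4 and 2%, 0%, 2% and 0% for a change of 2, with 2, 1, 7 and 1 unchanged genes called. Without any simulated change there were 0 calls in each comparison and fit. Alternatives covered the pseudocount, the filter, scaling, the block, the way library values were joined, symbols with several loci, the variance model, the samples in the fit, the threshold, the set test, and leaving out each library or batch. Positions of unnamed loci relative to genes used the GENCODE M21 annotation, after checking that 99.9% of 39030 symbols found once in both maps overlapped. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.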

Results

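Expression of 14607 genes was compared in 12 libraries, 3 each of sorted non-GC and GC B cells from Sle1b mice and from Sle1b mice labelled as lacking Ifnar1. The design asks how GC B cells differ from other B cells in this autoimmune-prone background, and what loss of type I interferon signalling changes in each cell type. Reads on named genes numbered 1459000 in Sle1b GC replicate 3 and 4204000 to 13647000 in the other 11 libraries. No pair of libraries held identical values, and the highest correlation between libraries was 0.916, between the non-GC libraries of replicate 1 of both genotypes.

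The 4 libraries of batch 3 stood apart from the other 8. They carried 21% (Sle1b non-GC), 57.1% (Sle1b GC), 27.3% (Ifnar1KO non-GC) and 36.9% (Ifnar1KO GC) of their reads on loci without a gene name, whereas the libraries of batches 1 and 2 carried 3.2% to 11.6%. The leading principal component held 58.3% of the variance and separated batch 3 from the rest. The cytoskeletal transcript Actb was listed at 5.78 FPKM in Sle1b GC replicate 3 and 11.5 FPKM in Ifnar1KO GC replicate 3, against 286.5 to 738.7 FPKM in the GC libraries of the other batches. Counts of changed genes are therefore also given for batches 1 and 2 alone with the filter redone on their 8 libraries, a fit added after seeing the data. The share on unnamed loci was also higher in GC than in non-GC cells in all 6 pairs of 1 genotype and batch: 6.6% against 3.2%, 5% against 4.5% and 57.1% against 21% in Sle1b, and 5.9% against 3.3%, 11.6% against 5.6% and 36.9% against 27.3% in Ifnar1KO. The ratio of such loci per Mb near expressed genes to those over 100 kb from any gene was lower in GC than in non-GC cells in batches 1 and 2 (Sle1b 2.60 against 65.1 and 16.2 against 88.0; Ifnar1KO 1.99 against 21.7 and 3.15 against 7.63) and higher in batch 3 (1.72 against 0.90 and 1.40 against 0.91). Library content thus differed along with cell type in every GC comparison below, and the design does not separate the 2.

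**Figure D1:**
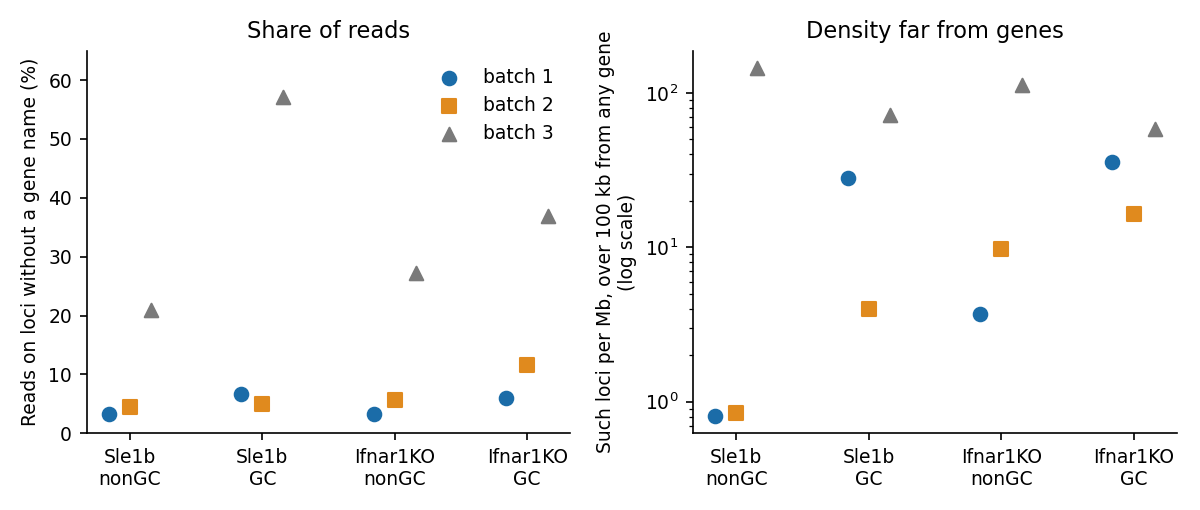
Reads on loci without a gene name in each of the 12 libraries (left, percent of reads) and the number of such loci with a value above 0 per Mb of sequence lying over 100 kb from any gene (right, log scale); each point is 1 library, marked by batch. The 4 libraries of batch 3 lie at 21% to 57.1% and the other 8 at 3.2% to 11.6%.

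Ifnar1, on chromosome 16 from 91485238 to 91507441 (GRCm38), was higher in the libraries labelled Ifnar1KO than in Sle1b in batches 1 and 2 and lower in batch 3, in both cell types. In non-GC cells it measured 14.5, 36.05 and 3.45 FPKM in Sle1b replicates 1, 2 and 3, and 51.1, 69.1 and 2.58 FPKM in the replicates labelled Ifnar1KO. In GC cells it measured 8.11, 9.88 and 6.80 FPKM in Sle1b, and 14.1, 15.4 and a listed 0 FPKM in the replicates labelled Ifnar1KO. The log2 fold change of Ifnar1KO against Sle1b was 0.80 (SE 0.75; limma, adjusted p = 1.00) in non-GC cells and -0.59 (SE 0.75, adjusted p = 0.881) in GC cells. Without Ifnar1KO GC replicate 3 the difference in GC cells was 0.00, and without batch 3 it was 0.65. The FPKM covers the whole locus, so reads on any part of the gene left by the targeting would count, and the value does not settle the genotype. Because the transcript goes against the label in batches 1 and 2, the libraries of the genotype B6.Sle1b.IFNaR1-/- are called labelled Ifnar1KO, and every direction between genotypes rests on those labels. Ifnar1KO below stands for the libraries labelled Ifnar1KO.

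In Sle1b mice, proliferation genes were higher and genes of resting B cells lower in GC than in non-GC cells. Of 47 cell cycle genes, 44 lay above 0, with a median log2 difference of 1.66, and the list as a whole rose (camera adjusted p = 2.2e-20; adjusted p = 0.252 with an estimated correlation). The proliferation marker Mki67 averaged 144 ± 128 FPKM (SD, n = 3) in GC cells and 1.52 ± 0.839 FPKM (SD, n = 3) in non-GC cells, a log2 difference of 4.77 (SE 0.88; 6.47, 6.22 and 1.61 in batches 1, 2 and 3), and the spindle factor Tpx2 differed by 4.55 (SE 0.63). Of 25 resting and follicular B cell genes, 24 lay below 0 with a median of -1.46. The list fell (camera adjusted p = 3.4e-10, 0.0158 with an estimated correlation, and 0.0804 with an estimated correlation in batches 1 and 2 alone). Its members included Cd55, which restrains complement (log2 -2.80, SE 0.52), the low-affinity IgE receptor Fcer2a (-2.08, SE 0.60) and the survival factor Bcl2 (-1.92, SE 0.54).

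Over all genes, 0 of 14607 passed limma's test at an adjusted p under 0.05 for GC against non-GC in Sle1b, with 1362 at an unadjusted p under 0.05. The smallest adjusted p, 0.0639, belonged to Tpx2 and to Iglc4, an immunoglobulin lambda locus listed at 0 in all 3 Sle1b GC libraries and at 8.94 to 30.7 FPKM in the non-GC libraries. With 1 library left out, 1 gene passed without Sle1b non-GC replicate 2, Sle1b GC replicate 2 or 3, or Ifnar1KO non-GC replicate 3, and 0 in the other fits. Without batch 3, 0 of the same 14607 genes passed. With the filter also redone on the other 8 libraries, a choice made after seeing the data, 13 of 12257 genes passed, 11 of them higher in GC cells. Mki67 rose by 6.35 (SE 0.45, adjusted p = 0.0029), the transcription factor Mybl1 by 5.78 (SE 0.51, adjusted p = 0.0064) and the GC confinement receptor S1pr2 by 5.01 (SE 0.61, adjusted p = 0.036). Top2a, Kif11, Ezh2, Neil1, Nuggc, Lpp and the switched immunoglobulin genes Ighg2b and Ighg2c were the other 8 that rose. Of the 2 lower ones, the predicted gene Gm23632 fell by 4.53 (SE 0.59), and Gm28900 was listed at 0 in both GC libraries.

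Genes of the GC programme followed the same direction. Of 29 germinal centre B cell genes, 21 lay above 0 with a median of 1.28, and the list rose (adjusted p = 3.7e-06; adjusted p = 0.267 with an estimated correlation). Adjusted over the list alone, 8 members were higher and 1 lower, against 0 over all genes. The higher members included S1pr2 (3.85, SE 0.86) and the costimulator Cd86 (2.04, SE 0.58), and the lower one was the follicle-homing receptor Cxcr5 (-1.64, SE 0.56). The dark zone list rose as well, with 13 of 15 members above 0 and a median of 1.66 (adjusted p = 4.0e-06; adjusted p = 0.252 with an estimated correlation), and 7 members were higher adjusted over the list alone. Antibody diversification and mismatch repair genes lay above 0 in 18 of 25 cases with a median of 0.83 (adjusted p = 2.2e-05; adjusted p = 0.306 with an estimated correlation) and none passed adjusted over the list alone. T-bet-associated B cell genes lay above 0 in 12 of 15 cases with a median of 1.12 (adjusted p = 2.3e-04; adjusted p = 0.252 with an estimated correlation), and the ectonucleotidase Nt5e (2.90, SE 0.67) was the 1 member past the threshold adjusted over the list alone. Light zone genes were not shifted as a list (median -0.27, 6 of 26 above 0, adjusted p = 0.521), although Egr2 (3.57, SE 0.71) and Cd86 were higher and Fcer2a was lower adjusted over the list alone.

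The cell cycle, GC B cell, dark zone and diversification medians came from batches 1 and 2. The cell cycle list had medians of 1.98, 2.93 and -0.02 in batches 1, 2 and 3, the GC B cell list 1.76, 1.77 and -0.05, the dark zone list 2.67, 2.99 and -0.05, and the diversification list 1.46, 1.84 and -0.12. The resting list had medians of -1.34, -1.08 and -1.53 and the light zone list -0.27, -0.42 and -0.34. The T-bet-associated list had medians of 0.636, 0.868 and 0.115, each below its median of 1.12 over fitted values. In the fit to batches 1 and 2, 30 of 47 cell cycle genes, 17 of 29 GC B cell genes and 12 of 25 diversification genes (median 1.69) were higher adjusted over the list alone.

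Interferon genes and marginal zone genes were lower in Sle1b GC cells, less so in batch 3. Medians in batches 1, 2 and 3 were -1.20, -0.89 and -0.28 for type I interferon-stimulated genes. They were -0.785, -0.763 and -0.099 for interferon-gamma-associated genes and -0.99, -0.80 and -0.20 for marginal zone genes. Of 53 type I interferon-stimulated genes, 41 lay below 0 with a median of -0.81 (adjusted p = 6.0e-05; adjusted p = 0.252 with an estimated correlation), and Rtp4 was the 1 member past the threshold adjusted over the list alone, at 2.35 to 7.65 FPKM in non-GC and 0 to 0.585 FPKM in GC libraries. Of 29 interferon-gamma-associated genes, 21 lay below 0 with a median of -0.57 (adjusted p = 0.00845; adjusted p = 0.199 with an estimated correlation), led by the class I light chain B2m (-3.30, SE 0.74, and -2.02 without batch 3). Marginal zone genes lay below 0 in 9 of 12 cases with a median of -0.76 (adjusted p = 0.0103; adjusted p = 0.252 with an estimated correlation), and 3 members, Cr2, Notch2 and Fcrl1, were lower adjusted over the list alone. The interferon-gamma-associated call ended without the batch block (adjusted p = 0.0567), without batch 2 (adjusted p = 0.0899) and without Sle1b non-GC replicate 2 (adjusted p = 0.0824). The marginal zone call ended without the block (adjusted p = 0.0827), without batch 1 (adjusted p = 0.229) and without Sle1b GC replicate 1 (adjusted p = 0.156). Among the 18 list calls made over all comparisons, 2 held with an estimated correlation and 3 with fry.

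Immunoglobulin constant regions split by class. In Sle1b GC cells, 4 of 11 members were higher and 2 lower adjusted over the list alone, and the list was not called (median 0.60, adjusted p = 0.226). It rose without Sle1b GC replicate 3, Sle1b non-GC replicate 3 or batch 3 (medians 1.38, 1.14 and 1.59; in the fit to batches 1 and 2, adjusted p = 0.332 with an estimated correlation). Ighg2b differed by 3.33 (SE 0.92), Ighe by 3.27 (SE 0.99) and Ighg1 by 3.01 (SE 0.88), whereas the lambda gene Iglc3 differed by -2.94 (SE 0.86). Without batch 3 Ighg1 differed by 4.54 and Iglc3 by -1.39, without batch 2 Ighg1 differed by 1.75, and without Sle1b non-GC replicate 3 Iglc3 differed by -1.77. MHC class II and antigen presentation genes had a median of -0.79 (11 of 14 below 0, adjusted p = 0.194), with H2-Aa (-2.78, SE 0.70, and -1.74 without batch 3) lower and Cd86 higher adjusted over the list alone, and the list fell without batch 3 (median -0.77, adjusted p = 0.00802; in the fit to batches 1 and 2, adjusted p = 0.599 with an estimated correlation).

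Other B cell and metabolic lists were not called by camera in Sle1b GC cells. Their medians were 0.14 for plasma cell and secretory genes, -0.39 for interferon receptor and signalling genes, -0.63 for nucleic acid sensing genes, -0.43 for B cell receptor signalling, -0.19 for cytokine and help receptors, -0.66 for SLAM family genes, -0.48 for apoptosis regulators, -0.57 for oxidative phosphorylation, 0.26 for glycolysis, -0.22 for Myc-associated growth genes, 0.15 for immediate early and heat shock genes and 0.95 for the 3 mitochondrially encoded items, with camera adjusted p of 0.0607 or higher. By fry, nucleic acid sensing genes (adjusted p = 0.0155) and oxidative phosphorylation genes (adjusted p = 0.0309) were lower. B cell receptor signalling was lower by camera without Ifnar1KO GC replicate 3, Sle1b GC replicate 1, Sle1b non-GC replicate 1 or batch 1 (medians -0.43, -0.60, -0.69 and -0.77). Nucleic acid sensing genes were lower without Sle1b GC replicate 1 or Ifnar1KO GC replicate 2 (medians -0.77 and -0.63), oxidative phosphorylation genes without Sle1b non-GC replicate 3 or batch 3 (-0.55 and -0.58), and plasma cell genes were higher without batch 3 (0.57). In the fit to batches 1 and 2, oxidative phosphorylation genes did not pass (adjusted p = 0.0551), and plasma cell genes had an adjusted p = 0.508 with an estimated correlation. The other calls made with a library left out were not tried with an estimated correlation. Markers of other cells were not called either, with medians of 0.41 for T cells, -0.57 for NK and cytotoxic cells, 0.34 for myeloid cells, -0.29 for plasmacytoid dendritic cells and 0.40 for erythroid cells and platelets. NK and cytotoxic genes were lower without Sle1b GC replicate 1, Sle1b non-GC replicate 3 or batch 1 (medians -1.02, -1.03 and -1.02), erythroid and platelet genes higher without Sle1b GC replicate 2, Sle1b non-GC replicate 2 or batch 2 (0.95, 0.88 and 1.15), and T cell genes higher without batch 2 (0.51). Adjusted over the list alone, the cathepsin inhibitor Cst3 (-3.72, SE 0.77) of the myeloid list and the receptor Klrk1 (-2.94, SE 0.65) of the NK list were lower. Of the 2 stromal and endothelial genes measured, Pecam1 differed by -0.66 and Sparc by 0.23. In batch 1 the erythroid and platelet median was 2.31 and the mitochondrial median 3.15, beside the cell cycle median of 1.98.

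**Figure D2:**
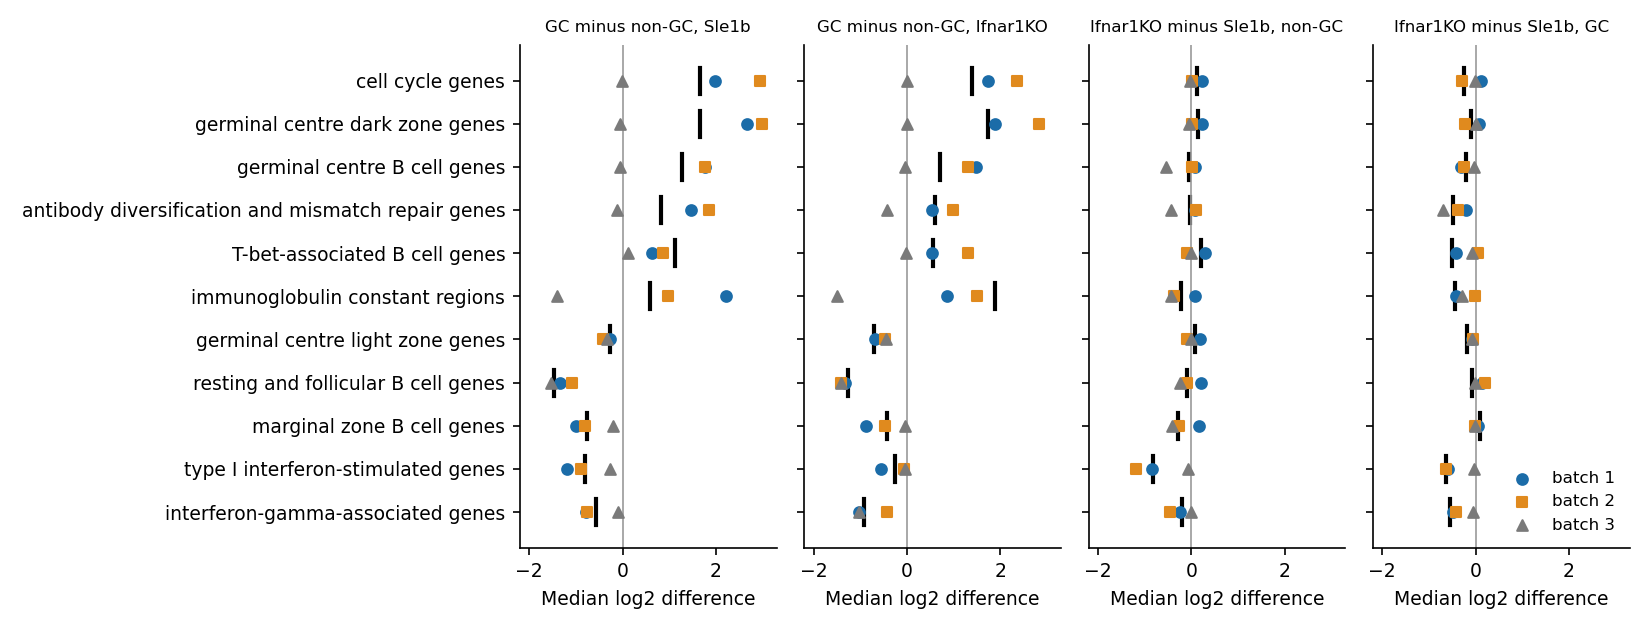
Median log2 difference of the members of 11 gene lists for GC minus non-GC cells in each genotype and for libraries labelled Ifnar1KO minus Sle1b in each cell type. Black bars are medians of fitted values over the 3 batches and points are medians within a batch; the cell cycle median for Sle1b lies at 1.98, 2.93 and -0.02 in batches 1, 2 and 3.

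In the libraries labelled Ifnar1KO, GC cells likewise had higher proliferation genes and lower resting B cell genes than non-GC cells. Of 47 cell cycle genes, 43 lay above 0 with a median of 1.40, and the list rose (adjusted p = 4.7e-21; adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone, 3 members were higher: Mki67 (4.36, SE 0.88), the topoisomerase Top2a (3.58, SE 0.91) and the cytokinesis factor Prc1 (2.12, SE 0.50). Of 25 resting and follicular genes, 23 lay below 0 with a median of -1.26, and the list fell (adjusted p = 1.7e-05; adjusted p = 0.0944 with an estimated correlation, and 0.0747 without the batch block). Adjusted over the list alone 9 members were lower, among them Fcer2a (-2.94, SE 0.60), Cd55 (-2.41, SE 0.52) and Bcl2 (-2.35, SE 0.54).

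GC B cell genes rose as a list (17 of 29 above 0, median 0.71, adjusted p = 3.6e-07; adjusted p = 0.332 with an estimated correlation), with none past the threshold adjusted over the list alone in 3 batches and 15 higher and 2 lower in the fit to batches 1 and 2 (median 1.45). Dark zone genes rose (11 of 15 above 0, median 1.73, camera adjusted p = 3.6e-07, and 0.332 with an estimated correlation). Adjusted over the list alone, 5 members were higher, among them Hmmr (2.57, SE 0.74) and Gcsam (2.51, SE 0.78). The item that holds Foxp1 (-1.43, SE 0.51) was the 1 lower member. Diversification and repair genes had a median of 0.60 (14 of 25 above 0, camera adjusted p = 0.00245, and 0.551 with an estimated correlation). Of their members, H2afx (2.77) was higher and Xrcc4 (-2.29) lower adjusted over the list alone. T-bet-associated genes had a median of 0.55 (11 of 15 above 0, camera adjusted p = 0.00191, and 0.332 with an estimated correlation). These rises were absent or reversed in batch 3: medians in batches 1, 2 and 3 were 1.73, 2.35 and 0.00 for cell cycle genes, 1.48, 1.30 and -0.04 for GC B cell genes, 1.88, 2.82 and 0.00 for dark zone genes, 0.53, 0.99 and -0.42 for diversification genes and 0.53, 1.30 and -0.02 for T-bet-associated genes. Resting genes had -1.33, -1.42 and -1.42. Immunoglobulin constant regions had a median of 1.89 (0.85 in batch 1, higher in batch 2 and -1.49 in batch 3; 6 of 11 above 0, adjusted p = 0.0194; adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone 6 of these constant regions were higher, led by Ighg1 (4.66, SE 0.88) and Ighg2b (3.77, SE 0.92), and 3 lambda genes were lower. Both calls ended without Ifnar1KO GC replicate 1 (medians 0.43 for diversification genes and 2.04 for constant regions), Ifnar1KO GC replicate 2 (0.13 and 1.30), Ifnar1KO non-GC replicate 1 (0.69 and 1.91), batch 1 (0.48 and 2.03) or batch 2 (-0.02 and 0.96), and that of constant regions also without Ifnar1KO non-GC replicate 2 (1.28) or with library medians set equal (adjusted p = 0.13). Both also ended with quantile normalization (0.66 and 2.44, adjusted p = 0.209 and 0.31). The T-bet-associated call ended without Ifnar1KO GC replicate 2 (median 0.23) or batch 2 (median -0.14).

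The interferon-stimulated list was not called for GC against non-GC cells in Ifnar1KO (median -0.25, 32 of 53 below 0, adjusted p = 0.875, with camera's direction up against a lower median of all genes). MHC class II and antigen presentation genes had a median of -0.92 (12 of 14 below 0, adjusted p = 0.123; fry adjusted p = 0.0109), and the list fell without batch 3 (median -1.04, adjusted p = 0.00864; in the fit to batches 1 and 2, adjusted p = 0.57 with an estimated correlation). Apoptosis regulators were not called as a list (median -0.23, adjusted p = 0.745), although 5 members were lower adjusted over the list alone, including Bcl2, Cflar (-1.96, SE 0.54) and Casp8 (-2.26, SE 0.65). By fry, which tests only whether members move one way, 10 of the 29 lists tested had an adjusted p under 0.05, all lower, in a comparison where the median of all genes was -0.40. Setting library medians equal moved that median to 0.08. Among these 10 lists, NK and cytotoxic genes (median -1.14) and plasmacytoid dendritic cell genes (median -0.98) lay below 0 in 6 of 6 members each (fry adjusted p = 0.0422 for both), without a call by camera (adjusted p = 0.106 and 0.285). Siglech and Klk1 of the plasmacytoid dendritic cell list were lower in batches 1 and 2 adjusted over the list alone, both listed at 0 in the GC libraries. The mitochondrial median was 2.32 in batch 1, 0.41 in batch 2 and -0.58 in batch 3. With 1 library left out, camera called NK and cytotoxic genes lower without Ifnar1KO GC replicate 3 (median -1.30). It called interferon-gamma-associated genes lower without Ifnar1KO non-GC replicate 2 (-1.265) and mitochondrially encoded items higher without Ifnar1KO non-GC replicate 3 (1.275).

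Over all genes, 3 of 14607 passed limma's test, all lower in GC cells of Ifnar1KO, with 1846 at an unadjusted p under 0.05. Iglc4 was listed at 0 in the 3 GC libraries and at 22.2 to 48.5 FPKM in the non-GC libraries (adjusted p = 0.0068), Ptcd2 fell by 3.99 (SE 0.56, adjusted p = 0.042), and the predicted gene Gm23850, outside the naming rule and named after its values were seen, was listed at 0 in the GC libraries and at 5.94 to 27.1 FPKM in the non-GC libraries (adjusted p = 0.042). No gene passed without the batch block, nor without batch 1, 2 or 3, Ifnar1KO GC replicate 3 or Ifnar1KO non-GC replicate 2 or 3. With Ifnar1KO GC replicate 1, Sle1b GC replicate 1 or 2, or Sle1b non-GC replicate 1 or 2 left out, 1 gene passed. The count without batch 3 became 42 of 12257 genes, 17 higher and 25 lower, only when the filter was also redone on the other 8 libraries after seeing the data. The higher genes included Mybl1 (5.97, SE 0.51), Mki67 (5.31, SE 0.45), Ighg2b (5.15, SE 0.46), Ighg2c (5.10, SE 0.58), Ighg1 (4.87, SE 0.65) and the GC nuclear factor Eaf2 (4.37, SE 0.62). The lower genes included Cd55 (-2.46, SE 0.37), the cathepsin Ctss (-2.99, SE 0.45), Zfp318 (-2.70, SE 0.42) and 6 immunoglobulin variable segments.

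**Figure D3:**
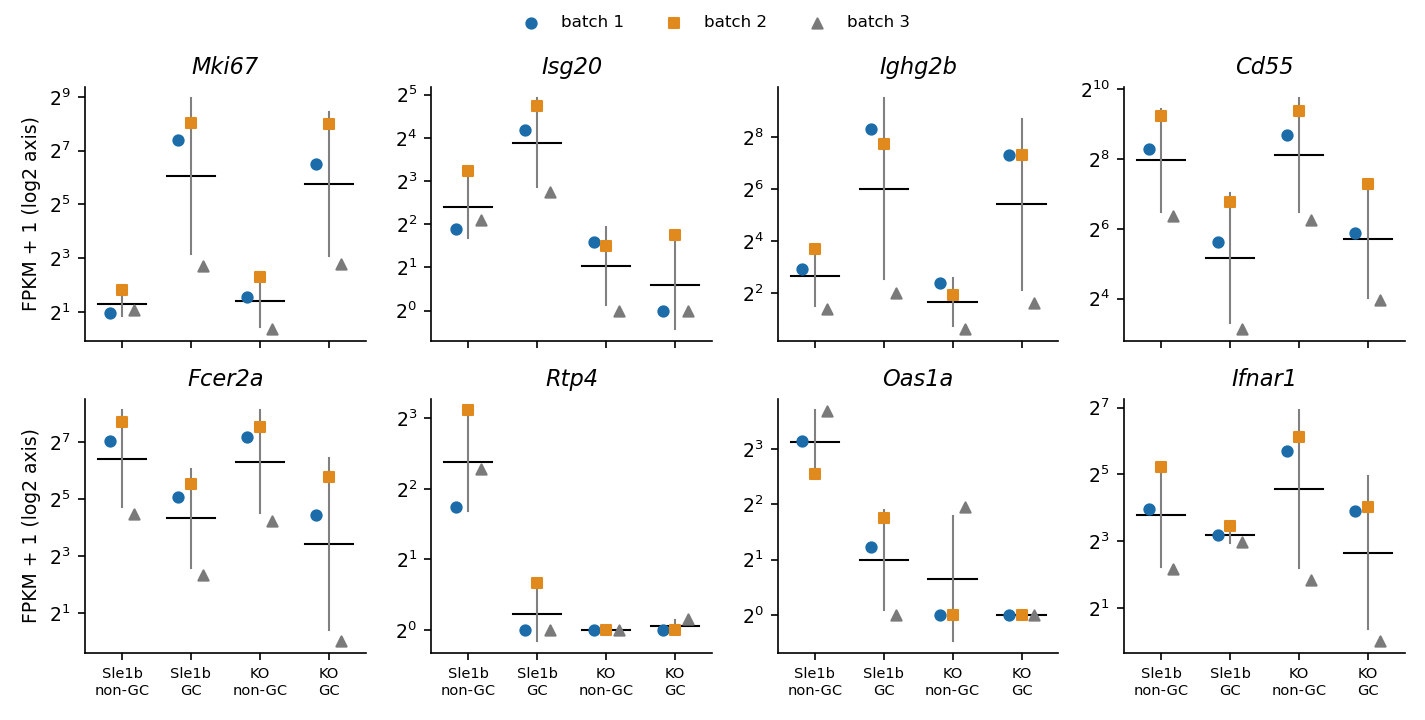
FPKM + 1 (log2 axis) of 8 genes in each library, by group and batch; horizontal lines are means on the log scale and vertical lines are 1 SD either side (n = 3 per group). KO stands for libraries labelled Ifnar1KO. In GC cells Mki67 lies at 90.8 to 258.6 FPKM in batches 1 and 2 and at 5.54 and 5.86 FPKM in batch 3.

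The GC change was similar in direction in both genotypes. Across the 14607 genes, which are not independent replicates, the log2 differences of GC against non-GC cells correlated between Sle1b and Ifnar1KO with Pearson's r of 0.404 and Spearman's rho of 0.375. Within batches 1, 2 and 3 the Pearson values were 0.443, 0.304 and 0.145. The 2 comparisons share no library, but they share the batches and, within 1 fit, each gene's variance estimate. Of the genes passing in batches 1 and 2 with the filter redone, 9 were higher in both genotypes (Mki67, Mybl1, Top2a, Kif11, S1pr2, Nuggc, Neil1, Ighg2b and Ighg2c), and 1 passed as lower in both. Independent lists of 11 and 17 genes would share 0.015. The shared variance estimates make these lists dependent, so 0.015 can be too low a comparison. The same GC change correlated between batches 1 and 2 with r of 0.273 in Sle1b and 0.27 in Ifnar1KO, and between batch 3 and either other batch with r of 0.072 or less.

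In non-GC cells, type I interferon-stimulated genes were lower in the libraries labelled Ifnar1KO than in Sle1b. Of 53 members measured, 43 lay below 0 with a median log2 difference of -0.82, and the list fell (camera adjusted p = 1.0e-19, and 0.0327 with an estimated correlation). A total of 25 members were lower in all 3 batches and 0 were higher in all 3, while 8.4% of all genes were lower in all 3. Adjusted over the list alone 4 members were lower, against 0 over all genes: the antiviral synthetases Oas2 (-2.13, SE 0.48) and Oas1a (-2.59, SE 0.69), the surface protein Ly6a (-2.58, SE 0.70) and Rtp4. Rtp4 measured 2.35, 7.65 and 3.88 FPKM in the Sle1b libraries and was listed at 0 in all 3 libraries labelled Ifnar1KO. Oas1a measured 7.92, 4.87 and 11.9 FPKM in the Sle1b libraries and a listed 0, a listed 0 and 2.89 FPKM in Ifnar1KO. Ly6a measured 223.7, 135 and 24.2 FPKM in Sle1b and 48.4, 13.4 and 4.07 FPKM in Ifnar1KO.

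The list's median was -0.84 in batch 1, -1.19 in batch 2 and -0.08 in batch 3. Fry did not call it (adjusted p = 0.0821), whereas leaving out any single library or batch kept camera's call. Without Sle1b non-GC replicate 2 the median was -0.54, and in members with a mean of at least 10 FPKM it was -0.432. In batches 1 and 2 alone the median was -1.03 (adjusted p = 6.3e-36; adjusted p = 0.159 with an estimated correlation), and 7 of 50 members were lower adjusted over the list alone, including Ifi27l2a (-4.11, SE 0.66), Xaf1 (-3.52, SE 0.82), Oasl2 (-2.57, SE 0.71) and Slfn5 (-2.67, SE 0.75). The pooled markers of other cells moved apart between batches beside this list, with a median of 0.27 in batch 1 and -0.19 in batch 2 over 57 genes.

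No other list was called between genotypes in non-GC cells over the 3 batches. Without Ifnar1KO non-GC replicate 3, interferon-gamma-associated genes (median -0.40), immunoglobulin constant regions (-0.88), nucleic acid sensing genes (-0.11), germinal centre B cell genes (-0.32) and cell cycle genes (-0.455) were lower. Without Sle1b non-GC replicate 3, interferon-gamma-associated genes were lower (-0.30) and cell cycle genes (0.62) and dark zone genes (0.75) higher. Interferon-gamma-associated genes had a median of -0.19 (17 of 29 below 0, adjusted p = 0.158), and in batches 1 and 2 alone they fell with a median of -0.34 (adjusted p = 3.5e-06; adjusted p = 0.262 with an estimated correlation). Nucleic acid sensing genes had a median of -0.32 (adjusted p = 0.158), with the RNA sensor Tlr7 at -2.16 (SE 0.82). Cell cycle genes had a median of 0.12, germinal centre B cell genes -0.06 and resting genes -0.09. Over all genes, 0 of 14607 passed limma's test, with 261 at an unadjusted p under 0.05, and 0 of 12257 passed in batches 1 and 2, with 221 at that level. Without Sle1b non-GC replicate 2, 1 gene passed over the 3 batches, and with array quality weights 4 genes passed, 1 higher and 3 lower. The smallest unadjusted p outside the list belonged to Pydc4, at 15.9 to 82.6 FPKM in Sle1b and 0 to 7.53 FPKM in Ifnar1KO (log2 -3.23, SE 0.61, adjusted p = 0.81). The higher genes with the smallest p, which did not pass, included Zswim1 (1.82, SE 0.46) and Apbb2 (2.88, SE 0.78).

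**Figure D4:**
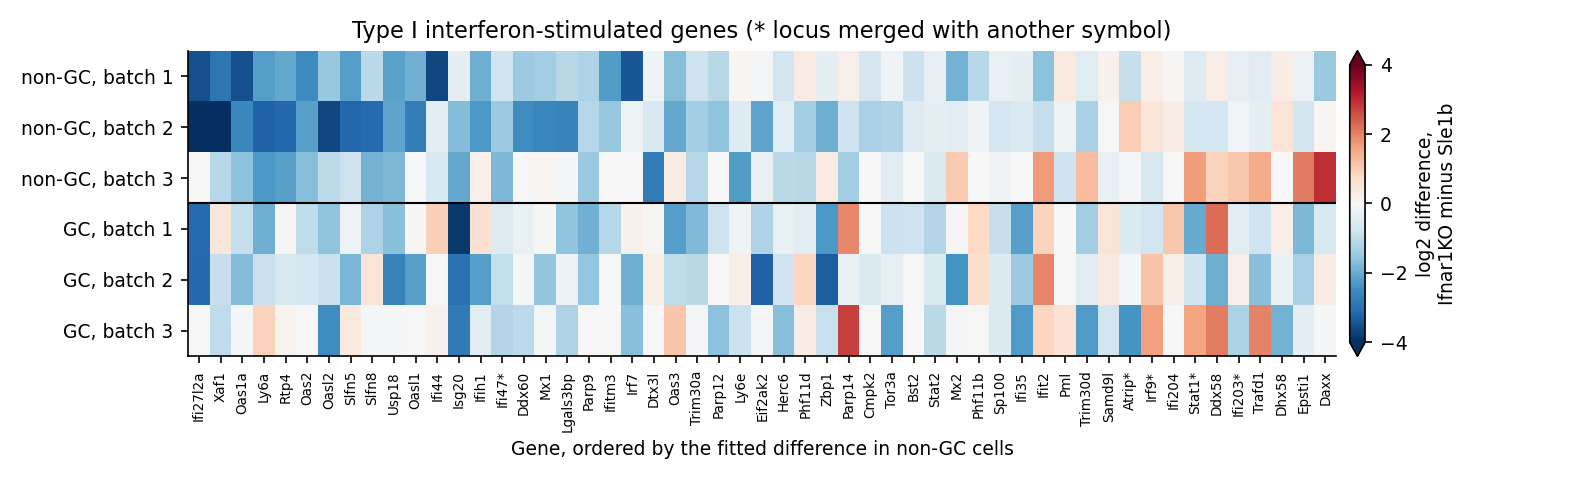
Log2 difference of libraries labelled Ifnar1KO minus Sle1b for the 53 type I interferon-stimulated genes measured (columns, ordered by the fitted difference in non-GC cells) in each cell type and batch (rows); the colour scale runs from -4 (blue) to 4 (red). In non-GC cells 44 members in batch 1, 48 in batch 2 and 33 in batch 3 lie below 0.

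In GC cells, interferon-stimulated genes were lower in most members but not called as a list. Of 53 members, 42 lay below 0 with a median of -0.63 (camera adjusted p = 0.256), where the median of all genes was -0.26. Setting library medians equal moved the median of all genes from -0.26 to 0.11 and the list's median to -0.25. The exonuclease Isg20 was lower adjusted over the list alone (log2 -3.22, SE 0.55), at 17.0, 25.7 and 5.67 FPKM in the Sle1b GC libraries and at 0, 2.38 and 0 FPKM in the Ifnar1KO GC libraries. The list fell without Ifnar1KO GC replicate 3 (median -0.74, adjusted p = 0.0124) and without Sle1b GC replicate 3 (median -0.63, adjusted p = 0.0326). In batches 1 and 2 alone it fell with a median of -0.74 (adjusted p = 0.0123; adjusted p = 0.968 with an estimated correlation), and 3 members were lower adjusted over the list alone, including the nucleic acid sensor Zbp1 (-2.81, SE 0.67).

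Interferon receptor and signalling genes lay below 0 in 14 of 17 cases with a median of -0.83, called by fry (adjusted p = 0.00482) and not by camera (adjusted p = 0.493). GC B cell genes had a median of -0.21, dark zone genes -0.10, light zone genes -0.18 and cell cycle genes -0.25, with camera adjusted p of 0.767 or higher. Without Sle1b GC replicate 3, cell cycle genes (-0.73) and diversification genes (-0.80) were lower. SLAM family genes, a list that holds receptors and adaptors, had a median of -0.31 (adjusted p = 0.801). The adaptor Sh2d1b1 was the 1 member lower adjusted over the list alone (-5.09, SE 1.36). It lay at -0.22, -5.29 and -9.75 in batches 1, 2 and 3, and at -2.96 without Sle1b GC replicate 3. Markers of other cells were lower in batch 1 beside these lists, with a pooled median of -0.76, and lay at 0.00 and -0.02 in batches 2 and 3. Over all genes, 0 of 14607 passed limma's test, with 932 at an unadjusted p under 0.05. Without Ifnar1KO GC replicate 2 or Sle1b GC replicate 2 or 3, 1 gene passed. Without batch 3, 0 passed, and with the filter also redone on the other 8 libraries 1 of 12257 passed, the predicted gene Gm28900, which was listed at 0 in the Sle1b GC libraries. Genes with the smallest p that did not pass included Plcxd2 (-3.96, SE 0.68, adjusted p = 0.335) and Mxd3 (adjusted p = 0.626), which was listed at 0 in all 3 Ifnar1KO GC libraries.

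The genotype differences of the 2 cell types were nearly uncorrelated across genes (Pearson's r 0.029). Within 1 cell type they correlated no better between batches, with r of 0.02 to 0.037 in non-GC and -0.021 to 0.005 in GC cells. The value between cell types therefore does not show that different genes changed in each. The interaction of genotype and cell type called 1 list, the interferon-stimulated genes, whose log2 difference between genotypes was less negative in GC than in non-GC cells (median difference 0.42, 36 of 53 above 0, adjusted p = 0.00115; adjusted p = 0.999 with an estimated correlation). Its batch medians were 0.28, 0.53 and 0.00, beside a median of all genes of -0.27, and setting library medians equal moved the latter to 0.05. Among its members Oas2 differed by 1.54 (SE 0.68), whereas Isg20 differed by -1.82 (SE 0.78). The call ended at a filter of 5 FPKM, with quantile normalization and with fry (adjusted p = 0.698). It also ended without batch 1 (0.42, adjusted p = 0.263) or batch 2 (0.34, adjusted p = 0.0813), without Sle1b non-GC replicate 1 (0.32, adjusted p = 0.132) or 2 (0.22, adjusted p = 0.179), without Ifnar1KO non-GC replicate 2 (0.30, adjusted p = 0.0843) and without Ifnar1KO GC replicate 3 (0.23, adjusted p = 0.104). With 1 library left out, camera also called diversification genes without Sle1b non-GC replicate 3 (median -1.04). It called constant regions without Ifnar1KO non-GC replicate 3 (median 0.94). Over all genes, 0 passed limma's test for the interaction, with 533 at an unadjusted p under 0.05, and 1 passed without Sle1b GC replicate 2. The genes with the smallest p, Plcxd2 (-4.51), Dguok (-4.75) and Kptn (4.26), had an adjusted p of 0.994.

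Genes near Ifnar1, which can carry sequence from the strain in which a knockout was made, were compared with the rest. Of 69 genes within 10 Mb, 2 had an unadjusted p under 0.05 for genotype in non-GC cells, against 259 of 14537 other genes (Fisher's exact test, two-sided, p = 0.35, odds ratio 1.65). In GC cells 4 of 69 did, against 928 of 14537 (Fisher's exact test, p = 1, odds ratio 0.903).

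In the authors' deposited tables, which compare 1 library with 1 other, 44 to 172 named loci were marked significant per table of batch 2, 51 to 228 in batch 1 and 693 to 1492 in batch 3. The authors' deposited table of non-GC cells between genotypes marked 51 named loci in batch 1, 44 in batch 2 and 1492 in batch 3.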

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

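The tests of exchanged labels, of the disrupted allele, of a shared scale factor, of genes near the floor, of other cells and of cell type or genotype as the source of unnamed loci were chosen only after the results were seen, and the other tests before. Each explanation below is a hypothesis found and tested on the same data.

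The 4 libraries of batch 3 carried 21%, 57.1%, 27.3% and 36.9% of their reads on loci without a gene name (Sle1b non-GC, Sle1b GC, Ifnar1KO non-GC and Ifnar1KO GC), a signal in data that the comparisons do not use. All 4 lay above all 8 other libraries, which argues against cell type or genotype alone, since each library has a counterpart of its group below it in batches 1 and 2. Transcripts running out of expressed genes would place these loci near expressed genes, and the lowest ratio of loci per Mb near expressed genes to loci per Mb over 100 kb from any gene was 0.9. Genomic DNA in the libraries may be the source, since that ratio was at most 1.72 in batch 3 and 1.99 to 88.0 in the other 8 libraries. The density of such loci on the X chromosome relative to autosomes was 0.78, 0.61, 0.76 and 0.69 in batch 3. It was 0.48 to 0.71 in the other 8 libraries, so it does not clearly set batch 3 apart. Every group is in the batch, so the design gives no other biological difference to set against genomic DNA.

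The Ifnar1 transcript was higher in the libraries labelled Ifnar1KO than in Sle1b in batches 1 and 2 and lower in batch 3, with fitted differences of 0.80 in non-GC and -0.59 in GC cells that did not pass the test. If loss of the receptor lowers interferon-stimulated genes, exchanged genotype labels in batches 1 and 2 would raise them in the libraries labelled Ifnar1KO. Yet their median lay at or below the 0.01 percentile of 10000 matched random lists in non-GC cells and the 0.64 percentile in GC cells. Each percentile sets 1 library against 1 other, with genes as units. In GC cells of batch 1 the pooled other-cell markers lay lower still (median -0.755, 0.01 percentile, against -0.602 for the list). That GC value therefore does not decide on labels. Because it takes the effect of the receptor for granted, this test gives that effect no support of its own. In batch 3 the percentiles were 22.2 and 55.9, so exchanged labels cannot be told apart there from labels as given. Transcript from the disrupted allele could give reads on Ifnar1 in the libraries labelled Ifnar1KO. This stays open because values over a whole locus do not show which exons were read. Such transcript need not exceed the level in Sle1b, and the source of the difference of 0.80 in non-GC cells was not tested. Leaving out batch 3, which held a listed 0 in Ifnar1KO GC replicate 3, gave a difference of 0.65 in GC cells.

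Interferon-stimulated genes were lower in the non-GC libraries labelled Ifnar1KO, a direction that rests on those labels, and a scale factor shared by all genes is argued against by a median of -0.765 with library medians set equal, as is sampling noise near the floor by a median of -0.432 in members with a mean of at least 10 FPKM. Fewer other cells in the Ifnar1KO sort could lower the list. In batch 1 the pooled other-cell markers lay at the 97.6 percentile of matched lists, which argues against a loss of all types together. The pool does not decide on a single type, since the types moved apart. In batch 1, medians were -0.867 for NK and cytotoxic genes and -0.458 for T cell genes. They were 0.157 for stromal and endothelial, 0.249 for plasmacytoid dendritic cell, 0.303 for myeloid and 0.669 for erythroid and platelet genes. In batch 2 the pooled markers lay at the 0.14 percentile. Other cells stay open in batch 2 and, for a single type, in batch 1. The pooled median of batch 2 was -0.185 (31 of 57 below 0) against -1.19 for the interferon-stimulated list. By type, batch 2 medians were -0.707 for NK and cytotoxic, -0.397 for T cell and -0.271 for myeloid genes. They were 0.12 for stromal and endothelial, 0.457 for erythroid and platelet and 0.684 for plasmacytoid dendritic cell genes. Because the types moved apart, the pooled median does not bound what a single type could add. Sorting on B220 does not settle this, since the purity of the sorts was not measured here. Of 10 splits of the 6 libraries, 1 (the real one) gave a camera p as small as 3.6e-21, the best other giving 8.9e-17 with the names of batch 3 exchanged, and 10 splits are too few for a share under 0.05. Loss of the receptor, the difference that the labels name, stays among the open explanations and may account for the pattern.

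The interaction was marked because the interferon-stimulated genes' genotype difference itself differed between cell types, by a median of 0.42 by camera, and this call ended with an estimated correlation (adjusted p = 0.999).

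The counts of changed genes were set against other splits of the same 6 libraries, and 10 splits are too few for a share under 0.05. For GC against non-GC in Sle1b the real count was 0 and the highest other 0, so 10 of 10 splits gave as many, and in Ifnar1KO the real count was 3 and the highest other 0, so 1 of 10 did. Between genotypes the real count was 0 in both cell types, with a highest other of 3 in non-GC and 1 in GC cells, so 10 of 10 splits gave as many. For the interaction all 32 exchanges of genotype names within cell type and batch gave the real count of 0. A real count of 0 is met by any split, so these 4 comparisons with a count of 0 say nothing about chance.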

How the results depend on the processing

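The fit to batches 1 and 2 and the restriction to members with a mean of at least 10 FPKM were chosen after seeing the data, and the other alternatives before. Of the 18 list calls, 18 were also made by camera at the preset correlation in batches 1 and 2. The same 18 were made with either other pseudocount, without a filter, with symbols of 1 locus, with array quality weights and with 1 ratio per batch. A filter of 5 FPKM or median centring kept 17, and quantile normalization 15. The interferon-stimulated list in non-GC cells stayed lower and past the threshold with camera at the preset correlation in every alternative run, and with an estimated correlation over the 3 batches (adjusted p = 0.0327) but not in batches 1 and 2 (adjusted p = 0.159). Where a call or count changed, the cause was not tested, except that fewer genes or libraries enter some fits.

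Camera with an estimated correlation called 1 list for GC against non-GC in Sle1b (9 with the preset), 0 in the libraries labelled Ifnar1KO (7 with the preset) and 0 for the interaction, where the interferon-stimulated median of 0.42 had an adjusted p of 0.999. Fry called 4 lists for GC against non-GC in Sle1b, 0 between genotypes in non-GC cells (interferon-stimulated median -0.82, adjusted p = 0.0821), 1 between genotypes in GC cells and 0 for the interaction (interferon-stimulated median 0.42, adjusted p = 0.698). Without a filter on level, camera called 16, 18, 7 and 2 lists for GC in Sle1b, GC in Ifnar1KO, genotype in GC cells and the interaction, and the interferon-stimulated list was lower between genotypes in GC cells (-0.58, adjusted p = 6.3e-06). The interaction lost its 1 list, leaving 0, with a filter of 5 FPKM (interferon-stimulated median 0.095, adjusted p = 0.64) and with quantile normalization (0.60, adjusted p = 0.0854). Array quality weights called 3 lists between genotypes in non-GC cells. In batches 1 and 2, 2 lists passed between genotypes in non-GC cells and 1 in GC cells, the interferon-stimulated genes (-0.74, adjusted p = 0.0123; adjusted p = 0.968 with an estimated correlation).

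For GC against non-GC in Ifnar1KO, the 3 genes past limma's threshold became 1 with a pseudocount of 0.1 or 3 FPKM, with median centring, with a robust variance or with array quality weights. They became 0 without a filter, with quantile normalization, with 1 ratio per batch or with the 6 libraries of both groups alone, and 42 without batch 3 and with the filter redone on the other 8 libraries. For GC against non-GC in Sle1b, 0 became 2 with a filter of 5 FPKM, 3 with array quality weights and 13 without batch 3 and with the filter redone. Leaving out batch 3 under the first filter gave 0 in both genotypes. Between genotypes, 0 became 4 in non-GC cells with array quality weights and 1 in GC cells without batch 3 and with the filter redone.

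Without the replicate block, 0 genes passed for GC against non-GC in Ifnar1KO, and 3 list calls ended: interferon-gamma-associated genes (adjusted p = 0.0567) and marginal zone genes (adjusted p = 0.0827) in Sle1b, and resting genes (adjusted p = 0.0747) in Ifnar1KO. NK and cytotoxic genes were called lower for GC cells in both genotypes without the block (medians -0.57 and -1.14). The block changed no other call of a list or a named gene.

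Each library and each batch was left out in turn, in 15 fits. The lists called numbered 9 (without Sle1b non-GC replicate 2) to 13 (without batch 3) for GC in Sle1b, 4 (without batch 2) to 8 (without batch 3) for GC in Ifnar1KO, 1 to 6 (without Ifnar1KO non-GC replicate 3) for genotype in non-GC cells, 0 to 3 (without Sle1b GC replicate 3) for genotype in GC cells, and 0 to 2 (without Sle1b non-GC replicate 3) for the interaction. Genes changed numbered 0 to 1 for GC in Sle1b, 0 to 3 for GC in Ifnar1KO, 0 to 1 for genotype in either cell type and 0 to 1 for the interaction. The interferon-stimulated median ranged from -1.08 to -0.54 for genotype in non-GC cells (adjusted p from 6.0e-38 to 2.6e-07), from -0.74 to -0.45 in GC cells and from 0.22 to 0.57 for the interaction. Ifnar1 ranged from 0.32 to 1.39 in non-GC cells and from -1.24 to 0.65 in GC cells, and the odds ratio of genes near Ifnar1 from 0 to 2.35 and from 0.213 to 1.99. Cell cycle genes were not called between genotypes, with a camera direction of up. They were higher in non-GC cells without Sle1b non-GC replicate 3 (0.62, adjusted p = 0.00852), and they were lower without Ifnar1KO non-GC replicate 3 in non-GC cells (-0.455, adjusted p = 0.0027) and without Sle1b GC replicate 3 in GC cells (-0.73, adjusted p = 0.0326). Each of these 3 fits leaves batch 3 with 1 library of the compared pair.

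Over all lists and alternatives, 101 results passed the threshold only under the alternative, 62 only without it and 2 changed direction. For named genes these numbers were 24, 35 and 0. A log2 change of 2 was recovered in 4% to 28% of simulated genes, so a gene not called says little about changes of that size.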

Other observations

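The test of type I against interferon-gamma-associated genes was chosen only after the result was seen, as were the genes of the next paragraph.

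Isg20 lay higher in Sle1b GC than in Sle1b non-GC libraries in each batch, opposite to Rtp4. It measured 2.69, 8.40 and 3.31 FPKM in Sle1b non-GC libraries and 17.0, 25.7 and 5.67 FPKM in Sle1b GC libraries. Cd55, the complement regulator, averaged 333 ± 261 FPKM (SD, n = 3) in Sle1b non-GC cells and 384 ± 296 FPKM (SD, n = 3) in non-GC libraries labelled Ifnar1KO, and the lower GC level was likewise seen in both genotypes, at 54.3 ± 50.1 and 75.3 ± 71.4 FPKM (SD, n = 3). Mxd3, which did not pass the test between genotypes, measured 22.7, 11.2 and 1.83 FPKM in Sle1b GC libraries. It was listed at 0 in all 3 GC libraries labelled Ifnar1KO.

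In non-GC cells the 53 type I interferon-stimulated genes had a median log2 difference of -0.82 and the 29 interferon-gamma-associated genes -0.19 between libraries labelled Ifnar1KO and Sle1b. The lists shared 0 genes, and the difference of medians, -0.63, had a two-sided permutation p of 0.014 over 100000 permutations of list names over genes, which are not independent replicates. In non-GC cells the loss thus fell more on the type I list, as a hypothesis that rests on the labels. The permutation did not match the lists on level. In GC cells the medians lay closer, at -0.625 for the type I list and -0.554 for the interferon-gamma-associated list (18 of 29 below 0).

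A total of 7 of the 60 listed interferon-stimulated genes had too few values at 1 FPKM or were absent, among them Isg15, Ifit1, Ifit3 and Rsad2. In the Sle1b non-GC libraries of batches 1 and 2 the measured members had a median of 9.04 FPKM.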
